A study of Homo sapiens with 18 samples.

How the data were processed

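Newly made and total RNA were measured in RPMI-8402 cells, an established human line of T-cell acute lymphoblastic leukaemia (T-ALL), by SLAM-seq. In this assay cells take up 4-thiouridine (4sU), alkylation of the RNA makes labelled bases read as T-to-C conversions, and reads with conversions stand for RNA made during labelling. Per the labels, cells received 1 µM CB-103 or 0.04% DMSO for 1, 4 or 24 h, with 100 µM 4sU over the same span, and 3′-end libraries were sequenced as single reads of 75 nt. The 18 libraries form 6 groups of 3 replicates. The labels give 1 batch and the design text calls the cells sorted, without naming a gate.

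The authors' pipeline, as the labels and file headers give it, used GRCh38, bcl2fastq 2.17, DESeq2 1.26.0 and slamdunk 0.3.4. The deposited gene tables of converted and of total reads hold raw counts for 19152 genes. The deposited table of normalised converted values is a signal: the authors divided each library's converted counts by 1 factor per library, which followed total and not converted reads. The deposited entries per untranslated region (UTR) hold counts of all, converted and multi-mapped reads, a signal of coverage and conversions over T positions, and reads scaled to the size of the library, a unit the authors' tool derived from the counts. The gene totals equalled the summed entries in 18 of 18 libraries. Of the genes, 11867 have overlapping entries, so a read can count more than once in a gene. Of the single converted reads, 92.9% carried 2 or more conversions. Converted reads are part of the total reads, so their results are not independent.

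Libraries held 12489335 to 38639187 reads. Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust dispersion, TMM scaling and filterByExpr, in 1 fit of the 6 group means with 12 residual degrees of freedom. Adjusted p is from Benjamini-Hochberg over all tested genes and a gene was called under 0.05. Converted and total counts were tested at each time, and so was the change of the effect between times in converted reads. The labelled share of a gene's reads was tested as the interaction of read type and treatment within the 6 libraries of a time, with the library as a block. CPM are counts scaled to the effective size of the library, log2 fold changes are CB-103 against DMSO with the standard error of the fit, and list tests used a prior count of 2. A gene is said to rise or fall against DMSO of the same time, not against an earlier time. Where the 3 libraries of a group held 0 reads, a bound on the fold against a floor of 3 reads over the group is given for genes with 1 UTR entry only. Bounds and intervals cover counting error only and not the spread between replicates. Bounds treat reads as independent, and the interval of a share of genes treats genes so. Reads carried no molecular identifiers, so copies of 1 molecule can count as several reads, which the bounds leave out.

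There were 23 gene lists, fixed before the data were examined, as were the comparisons and the rule for named genes. They covered Notch targets described in T-ALL, other Notch pathway genes, ribosome biogenesis, metabolic MYC targets, cholesterol synthesis and uptake, aryl hydrocarbon receptor targets, the integrated stress and unfolded protein responses, NRF2, heat shock, p53, immediate early genes, G1/S, G2/M, T-cell identity, T-ALL transcription factors, FOXO, apoptosis, interferon, NF-kappaB, glycolysis with hypoxia, and markers of B cells, myeloid cells and stroma. A list with at least 5 tested genes was tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. Adjusted p of lists is over all lists and times of a read type. List members were also adjusted over the list alone.

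Named genes were, at each time in converted reads, the 10 higher and 10 lower called genes with the largest fold change among those whose groups did not overlap, up to 4 called members of each list, and HES1, HES4, DTX1, NRARP, NOTCH1, NOTCH3, MYC, PTCRA, IL7R and IGF1R, called or not. In total reads and labelled shares they were 5 higher and 5 lower genes. Where the rule gave fewer than 5, the 5 of smallest p were taken. NRARP and PTCRA had too few reads for the tests, as had NOTCH3 and IL7R in converted reads. Means per library were compared by exact two-sided permutation tests, whose smallest possible p for 3 against 3 is 0.1.

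Alternatives were RLE scaling, DESeq2 1.42.0 (Wald test), no filter, a filter of 20 reads in 3 libraries, only the 6 libraries of a time, the replicate number as a block, a 2-fold threshold, scaling of converted reads from total reads, and leaving out each library in turn. A single UTR entry per gene, the authors' size factors, and fits without the 1 h libraries were added after the data were seen. In tests on simulated data, 100 genes were changed 2-fold and 100 changed 4-fold and the share recovered was counted. The numbers of the replicates did not pair the libraries: of 9 pairs with the same number, 0 in converted and 1 in total reads had a correlation of residuals above 0.1. Counts of replicates differed by more than read sampling (chi-square per degree of freedom 5.09 to 54.6 in converted reads), and no pair of replicates was identical. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples only. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Some genes of the lists are not reported here by name.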

Results

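SLAM-seq profiles were collected from RPMI-8402 cells treated with CB-103, which the study's title describes as a disruptor of the Notch transcription factor complex, or with DMSO, for 1, 4 or 24 h, with 3 libraries in each of the 6 groups. Libraries held 26378092 to 38639187 reads at 1 h, 21180335 to 27178948 at 4 h and 12489335 to 17159973 at 24 h. Converted reads, which stand for RNA made during labelling, were 0.185% ± 0.0437 of the counts of the deposited gene tables in DMSO and 0.136% ± 0.00992 in CB-103 libraries at 1 h (SD, n = 3, exact permutation p = 0.2). At 4 h they were 12.04% ± 0.722 and 11.5% ± 0.262 (SD, n = 3, exact permutation p = 0.4). At 24 h the share was 33.2% ± 0.450 in DMSO and 19.9% ± 1.15 in CB-103 libraries, with no overlap (SD, n = 3, exact permutation p = 0.1, the smallest possible). Reads in 1 UTR entry per gene, the entry with most reads, also made up less of the library at 24 h. They were 56.4% ± 5.32 in DMSO against 36.3% ± 0.791 with CB-103 (SD, n = 3, exact permutation p = 0.1). Scaling of converted reads from total reads moved the median log2 change of all genes to -0.19 at 4 h and -0.64 at 24 h, against -0.03 and -0.04 with scaling from converted reads. Changes of converted reads below are therefore relative to the other labelled RNA. Total reads were scaled by TMM or RLE as well, so their changes are relative to the other counted RNA. Every library received 4sU, so none measures the background of conversions. How much of the few converted reads at 1 h is background is therefore not known.

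**Figure D1:**
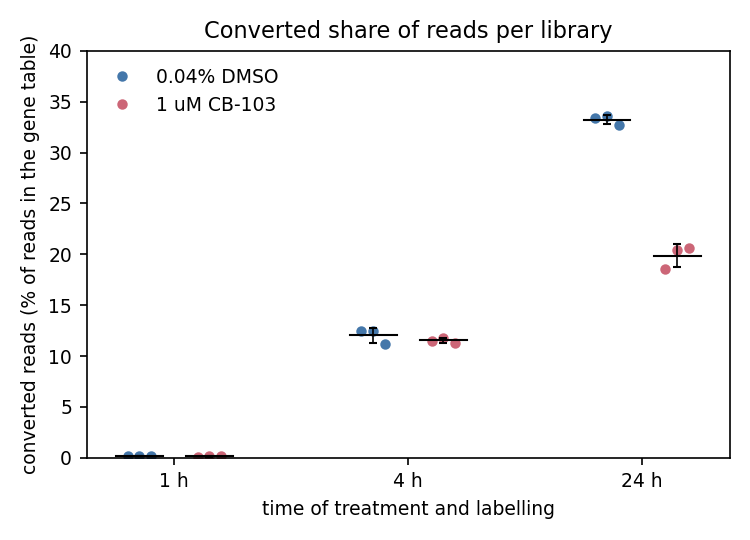
Converted counts as a percent of the total counts of the deposited gene tables, by time in h and treatment. Each point is a library and each bar the SD around the mean of 3 libraries. At 24 h the CB-103 libraries have a mean of 19.9% and the DMSO libraries of 33.2%.

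The comparison at 1 h asked which newly made transcripts differ soonest after CB-103. HES1, a transcriptional repressor and direct Notch target, had 1931 ± 531 CPM of converted reads in DMSO and 2271 ± 290 in CB-103 libraries (SD, n = 3; log2 change 0.23 ± 0.32, SE, adjusted p = 0.824). MYC, a growth regulator and Notch target in T-ALL, had a log2 change of 0.37 ± 0.46 (adjusted p = 0.762), and NOTCH1 had -1.34 ± 0.77 (adjusted p = 0.344). Among called genes, PDLIM2 had 61 converted reads in DMSO and 0 in CB-103 libraries (adjusted p = 0.00295). ATP6AP2 had 51 and 0 (adjusted p = 0.00312), while GUSB had 0 and 34 (adjusted p = 0.00713). These genes have several UTR entries, so the counts can hold a read more than once and no bound on the fold is given. DNAJA1, which encodes a heat shock protein 40 co-chaperone, was the member of the heat shock list that fell, by 1.65 ± 0.37 on the log2 scale (adjusted p = 0.0298), but not in 2 of the 6 fits that left out a library.

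In all, 177 of 9875 genes were called at 1 h, 79 higher and 98 lower, and in 93 of them a group had 0 reads. With a single UTR entry per gene 3 were called, and with only the 6 libraries of 1 h edgeR called 0 of 1426 tested genes (33 at an unadjusted p below 0.05), a fit that tested 34 of the 177, while DESeq2 in the fit of all libraries called 1191. Scaling from total reads gave 68 higher and 284 lower, and the authors' size factors 69 and 282. The count was 351 without DMSO replicate 2, 281 without CB-103 replicate 2, and 270 without CB-103 replicate 3. None of the 19 lists was called by camera, while fry called the T-cell identity list lower (adjusted p = 0.00478). The Notch target list had 13 tested genes, a median log2 change of -0.73 and an adjusted p of 0.48, with 0 genes called over all genes and 0 when adjusted over the list alone. Simulated 4-fold changes were recovered in 11.1% of genes and 2-fold changes in 2.04%, so most differences of that size were missed in the simulation. It drew each count independently and gave 13 calls with 0 false, while splits of the real 1 h libraries gave 89 to 250. The recovery may therefore not hold for the real reads of 1 h. In total reads edgeR called 0 of 12272 genes (616 at an unadjusted p below 0.05) and DESeq2 called 0 (770 unadjusted), with 50.5% of simulated 2-fold changes recovered. HES1 total reads were 85.0 ± 6.31 CPM in DMSO and 83.6 ± 6.95 with CB-103 (SD, n = 3; log2 change -0.02 ± 0.21). The gene with the smallest p, NSG1, had 68 total reads in DMSO and 0 in CB-103 libraries (adjusted p = 0.904), and 0 of 21 lists were called by camera.

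At 4 h, transcripts of the integrated stress and unfolded protein responses were higher together in newly made RNA with CB-103 than in DMSO of 4 h. CHAC1, a glutathione-degrading enzyme, went from 1.18 ± 0.625 to 91.3 ± 10.5 CPM (SD, n = 3; log2 change 6.25 ± 0.66, SE, adjusted p = 7.4e-06). DDIT3, which encodes the transcription factor CHOP, went from 41.7 ± 12.6 to 1222 ± 46.5 CPM (log2 change 4.87 ± 0.47, adjusted p = 3.1e-06). SESN2, a stress-induced sestrin, rose by 4.96 ± 0.47 on the log2 scale, TRIB3, a pseudokinase, by 4.31 ± 0.41, and HERPUD1, which acts in degradation of proteins from the endoplasmic reticulum, by 5.21 ± 0.68. Of the 22 tested genes of the list, 13 rose, 0 fell and 9 were not called, and 19 rose when adjusted over the list alone (median log2 change 2.21, adjusted p = 1.47e-44, and 1.22e-07 with an estimated correlation). The NRF2 list, of the oxidative stress response, was higher with 1 of 11 genes called and 3 adjusted over the list alone (median 0.66, adjusted p = 2.16e-05). The called member was SLC7A11, the cystine transporter that the stress list also holds, at 2.70 ± 1.23 and 117 ± 20.1 CPM (log2 change 5.42 ± 0.55). Cholesterol genes were higher as a list (2 of 19 called, 3 adjusted over the list alone, median 0.54, adjusted p = 0.000511). INSIG1, a sterol-regulated retention protein of that list, had a log2 change of 0.97 ± 0.23. Its call ended in each of the 6 fits without a library (adjusted p = 0.112 to 0.234) and with scaling from total reads (0.212).

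HES1 fell by 1.66 ± 0.32 on the log2 scale in newly made RNA at 4 h, from 337 ± 7.90 to 107 ± 8.49 CPM (SD, n = 3; adjusted p = 0.0117). That call was kept without the 1 h libraries and without DMSO replicate 3. It was lost without any other library of 4 h (adjusted p up to 0.0853) and with the replicate as a block (0.0996). TNFSF10, which encodes the death ligand TRAIL, fell by 1.95 ± 0.36, a call that ended without CB-103 replicate 2 (adjusted p = 0.0525) or 3 (0.0795). DTX1, a regulator of Notch signalling, had a log2 change of -1.24 ± 0.42 (adjusted p = 0.261), NOTCH1 of -1.09 ± 0.50 (0.502), MYC of -0.17 ± 0.42 (0.983), HES4 of -0.11 ± 0.51 (0.992) and IGF1R of -0.70 ± 0.51 (0.799). Without the 1 h libraries DTX1, NOTCH1 and IGF1R were called (adjusted p = 0.0202, 0.0196 and 0.0470), while MYC and HES4 were not (0.807 and 0.820). The Notch target list was lower by camera, with 1 of 13 genes called and 3 when adjusted over the list alone (median -0.70, adjusted p = 0.0140), a call lost with an estimated correlation (adjusted p = 0.140). The G2/M list (0 of 20 called, 0 adjusted over the list alone, adjusted p = 0.00260) and the T-cell identity list (0 of 15 called, 3 lower adjusted over the list alone, adjusted p = 0.00663) were lower too. Both calls were lost with an estimated correlation (adjusted p = 0.0943 and 0.0597).

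Genes outside these lists or in lists without a call also changed at 4 h. JUN, a subunit of the AP-1 transcription factor, rose by 5.97 ± 0.59 on the log2 scale, from 1.39 ± 1.29 to 94.0 ± 30.2 CPM (SD, n = 3; adjusted p = 3.1e-06). RGS2, a regulator of G-protein signalling, rose by 5.55 ± 0.60 and ICOS, a co-stimulatory receptor of T cells, by 5.08 ± 0.76. BBC3, which encodes the pro-apoptotic protein PUMA, rose by 4.20 ± 0.67, CXCL8, a chemokine, by 4.90 ± 0.74, NFKBIA, the inhibitor of NF-kappaB, by 1.92 ± 0.32, and VEGFA, an angiogenic factor, by 2.54 ± 0.41. Of the immediate early list 2 genes rose (JUN and IER3), while JUNB and EGR1 had log2 changes of -2.23 ± 0.46 and -2.43 ± 0.56, with calls lost in 3 and 5 of the 6 fits without a library.

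In total 70 of 9875 genes were called in converted reads at 4 h, 60 higher and 10 lower. The balance of higher and lower genes depended on the fit. The fit without the 1 h libraries called 637 with all 70 among them (339 higher, 298 lower), DESeq2 called 516 (299 and 217), only the 6 libraries of 4 h gave 615 (354 and 261), a single UTR entry per gene 308 (195 and 113), and the replicate as a block 30 (29 and 1). Leaving out DMSO replicates 1, 2 or 3 gave 29, 32 and 40 genes, and leaving out CB-103 replicates 1, 2 or 3 gave 41, 47 and 39. Simulated changes of 4-fold were recovered in 60% of genes and of 2-fold in 2%. Of the 38 named called genes, 19 kept the call in every fit without a library, among them CHAC1, DDIT3, SESN2, TRIB3, HERPUD1, SLC7A11, JUN, RGS2, ICOS, BBC3, CXCL8, IER3, NFKBIA and VEGFA.

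**Figure D2:**
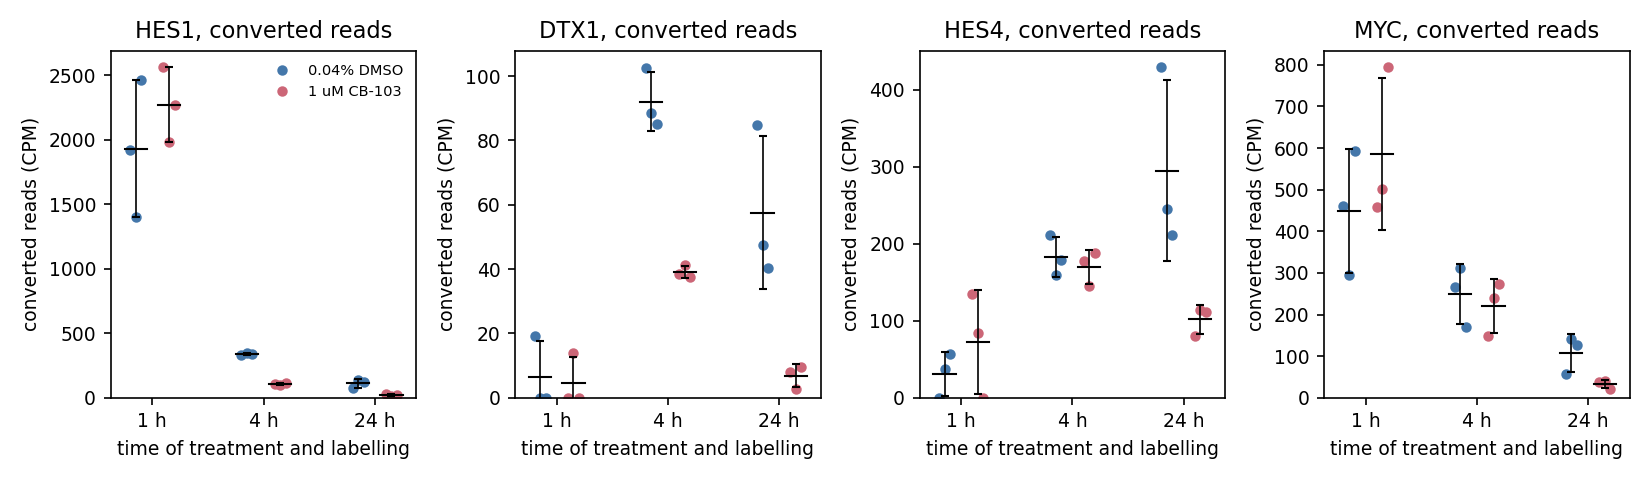
Converted reads of HES1, DTX1, HES4 and MYC in CPM by time in h and treatment, 1 panel per gene. Points are libraries, lines the mean of 3 and bars the SD. HES1 has means of 337 CPM in DMSO and 107 with CB-103 at 4 h, and of 113 and 22.8 at 24 h.

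Total RNA, old and new together, showed the fall of HES1 at 4 h as well, from 83.4 ± 8.65 to 27.9 ± 4.07 CPM (SD, n = 3; log2 change -1.58 ± 0.22, SE, adjusted p = 9.89e-05), a call kept without any 1 of the 6 libraries. NOTCH1 fell by 0.83 ± 0.22 (adjusted p = 0.0265), a call lost in 4 of the 6 fits without a library (adjusted p up to 0.123). DTX1 fell by 0.72 ± 0.21 (adjusted p = 0.0466), a call lost in all 6 (adjusted p = 0.0730 to 0.163). MYC, HES4, IGF1R, NOTCH3 and IL7R were not called in total reads at 4 h. The Notch target list was lower, with 4 of 16 genes called and 4 adjusted over the list alone (median -0.36, adjusted p = 0.0111). The stress list was higher (18 of 22 rose, 18 adjusted over the list alone, median 1.54, adjusted p = 1.02e-30) and so was the cholesterol list (6 of 20 rose, 8 adjusted over the list alone, adjusted p = 0.000186). Unscaled counts in DMSO also differed between times, which was not tested. TRIB3 had 1570, 1318 and 1744 in DMSO at 1 h, 118, 120 and 135 at 4 h, and 1648, 1731 and 2285 with CB-103 at 4 h. For DDIT3 these were 936, 783 and 1053, 426, 435 and 189, and 11103, 10146 and 13008. A higher value than DMSO at 4 h is therefore not always a rise over 1 h. NRF2 genes were higher with 4 rising and 1 falling of 12, and 4 and 1 adjusted over the list alone (adjusted p = 0.0276), but not with an estimated correlation (adjusted p = 0.0669). G2/M genes were lower (4 of 20 fell, 5 adjusted over the list alone, adjusted p = 0.00205), but not with an estimated correlation (adjusted p = 0.141). Camera called these 5 of 21 lists, while fry called 12, the same 5 among them. DGAT2, which makes triglycerides, fell from 4.10 ± 1.10 to 0.0683 ± 0.118 CPM, and CYP39A1, an oxysterol hydroxylase, had 0 reads in DMSO and 196 with CB-103, at least 54.4-fold higher (adjusted p = 0.00302). In all, 945 of 12272 genes were called, 491 higher and 454 lower. DESeq2 called 1481, only the 6 libraries gave 1725, and the replicate block gave 502. Leaving out DMSO replicates 1, 2 or 3 gave 517, 578 and 607 genes, and leaving out CB-103 replicates 1, 2 or 3 gave 625, 575 and 581. Simulated 2-fold changes were recovered in 49.5% of genes and 4-fold changes in 84.7%.

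After 24 h, newly made RNA of Notch target genes was lower as a list. RHOU, a small GTPase, fell by 4.14 ± 0.33 on the log2 scale, from 799.9 ± 93.9 to 45.4 ± 2.76 CPM (SD, n = 3; adjusted p = 7.86e-08). DTX1 fell by 3.07 ± 0.49, from 57.6 ± 23.9 to 6.83 ± 3.58 CPM (adjusted p = 0.000661), and HES1 by 2.31 ± 0.34, from 113 ± 33.6 to 22.8 ± 6.81 CPM (adjusted p = 0.000292). MYC fell by 1.71 ± 0.45 (adjusted p = 0.025), but this call was kept only without DMSO replicate 1 and lost without any other library (adjusted p up to 0.142) and with the replicate as a block (0.0718). HES4 had a log2 change of -1.54 ± 0.53 (adjusted p = 0.0857), NOTCH1 of -1.51 ± 0.53 (0.0912) and IGF1R of -0.16 ± 0.52 (0.892). HES4 and NOTCH1 were called without the 1 h libraries (adjusted p = 0.000442 and 0.00149). Of the 13 tested Notch targets 5 fell, 0 rose and 8 were not called, 9 fell when adjusted over the list alone, and 0 had a positive log2 change (median -1.51, adjusted p = 1.99e-07, and 0.00585 with an estimated correlation).

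Genes of T-cell identity also fell at 24 h. LAT, an adaptor of the T-cell receptor, fell by 3.02 ± 0.45 on the log2 scale (adjusted p = 0.000505), DNTT, the terminal transferase of immature lymphocytes, fell by 2.98 ± 0.48, CD2, an adhesion molecule of T cells, fell by 4.32 ± 0.69 and BCL11B, a factor of T-lineage commitment, by 1.98 ± 0.34. In that list 7 of 15 genes fell, 0 rose and 10 fell when adjusted over the list alone (median -1.53, adjusted p = 7.55e-09). Among transcription factors of T-ALL 4 of 18 fell and 11 fell when adjusted over the list alone (median -1.05, adjusted p = 1.5e-05), ERG by 1.93 ± 0.31 (from 339 ± 9.11 to 88.7 ± 11.2 CPM, SD, n = 3). PECAM1, an adhesion molecule, fell by 2.36 ± 0.42.

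The stress response list was higher at 24 h, though not in every member called at 4 h. HSPA5, the chaperone of the endoplasmic reticulum, went from 201 ± 27.6 to 3281 ± 464 CPM (SD, n = 3; log2 change 4.03 ± 0.38, SE, adjusted p = 1.07e-06), and PPP1R15A, a phosphatase subunit that ends the stress block on translation, from 43.9 ± 2.13 to 679 ± 50.3 (3.95 ± 0.41). Of the 22 genes of that list 11 rose, 0 fell and 12 rose when adjusted over the list alone (median 1.68, adjusted p = 5.98e-15). CHAC1 (log2 change 0.09 ± 0.58, adjusted p = 0.953) and PSAT1 (0.24 ± 0.48, 0.821) were called at 4 h and not at 24 h. Heat shock genes rose in 5 of 13 (7 adjusted over the list alone, median 0.69, adjusted p = 3.54e-06), with BAG3, a co-chaperone, at 2.21 ± 0.44 and DNAJB1 at 2.76 ± 0.57. HSPA1B and HSPA1A had log2 changes of 5.40 ± 0.42 and 4.88 ± 0.42, but their sequences are near identical and can share reads, so the split between them is uncertain. NRF2 genes rose in 5 of 11 (6 adjusted over the list alone, median 1.32, adjusted p = 0.000132), among them the ferritin genes FTL (2.09 ± 0.31) and FTH1 (1.32 ± 0.20), which store iron. Cholesterol genes rose in 6 of 19 (9 adjusted over the list alone, median 1.00, adjusted p = 3.13e-07), with HMGCS1, an early enzyme of the pathway, at 105 ± 10.3 and 1048 ± 85.6 CPM (log2 change 3.32 ± 0.41).

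Lists of growth and division genes were lower at 24 h. TFRC, the transferrin receptor, fell by 1.68 ± 0.35 on the log2 scale (adjusted p = 0.00517), and 6 of the 23 metabolic MYC targets fell (6 adjusted over the list alone, median -0.87, adjusted p = 0.00228, and 0.0247 with an estimated correlation). Ribosome biogenesis genes fell in 3 of 30 (3 adjusted over the list alone, median -0.47, adjusted p = 0.0265, and 0.0471 with an estimated correlation). G1/S genes fell in 3 of 22, while CDC6, which loads the replicative helicase, rose by 1.97 ± 0.43 (4 lower and 1 higher adjusted over the list alone, median -0.66, adjusted p = 0.0147). The call of CDC6 was lost in 2 of the 6 fits without a library. UNG, a uracil glycosylase of DNA repair, fell by 2.03 ± 0.39. G2/M genes fell in 2 of 20 (2 adjusted over the list alone, adjusted p = 0.0179), a list call lost with an estimated correlation (adjusted p = 0.179).

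The largest called increases included CXCL8, at 0.569 ± 0.288 and 961 ± 93.7 CPM (SD, n = 3; log2 change 10.58 ± 0.75, adjusted p = 3.07e-08), and HSPA6, an inducible heat shock protein, at 0.239 ± 0.236 and 94.2 ± 6.92 CPM (8.43 ± 0.77). CLU, which encodes the chaperone clusterin, had 0 converted reads in DMSO and 237 with CB-103, and GLT1D1 had 110 and 0, counts that can hold a read more than once. C3AR1, a complement receptor with 1 UTR entry, had 0 and 105, at least 91.1-fold higher. CCL4L2, with 7 UTR entries, had 0 and 84, but shares reads with its paralogs and was not called by DESeq2 (adjusted p = 0.160). Lists not called by camera at 24 h were other Notch pathway genes (adjusted p = 0.193), p53 (0.480), immediate early (0.0814), FOXO (0.917), apoptosis (0.929), interferon (0.176), NF-kappaB (0.0814) and glycolysis with hypoxia (0.692), of which fry called NF-kappaB higher (0.00478). Members of them moved both ways: of the interferon list ISG20, an exonuclease, rose by 2.81 ± 0.44, while IFI6 had -2.01 ± 0.41 with a call lost in 2 of 6 fits without a library.

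Together 636 of 9875 genes were called in converted reads at 24 h, 299 higher and 337 lower. Scaling from total reads gave 155 higher and 1623 lower, the fit without the 1 h libraries 2766 genes with all 636 among them, DESeq2 1970, a single UTR entry per gene 1784, only the 6 libraries of 24 h 2849 and the replicate block 405. Leaving out DMSO replicates 1, 2 or 3 gave 377, 208 and 249 genes, and leaving out CB-103 replicates 1, 2 or 3 gave 220, 234 and 266. Simulated 4-fold changes were recovered in 44.1% of genes and 2-fold changes in 5.21%. The calls of RHOU, HES1, DTX1, LAT, DNTT, CD2, BCL11B, ERG, PECAM1, HSPA5, PPP1R15A, BAG3, DNAJB1, FTL, FTH1, HMGCS1, TFRC, UNG, CXCL8, HSPA6, CLU, C3AR1, GLT1D1 and ISG20 were kept in each fit without 1 library.

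**Figure D3:**
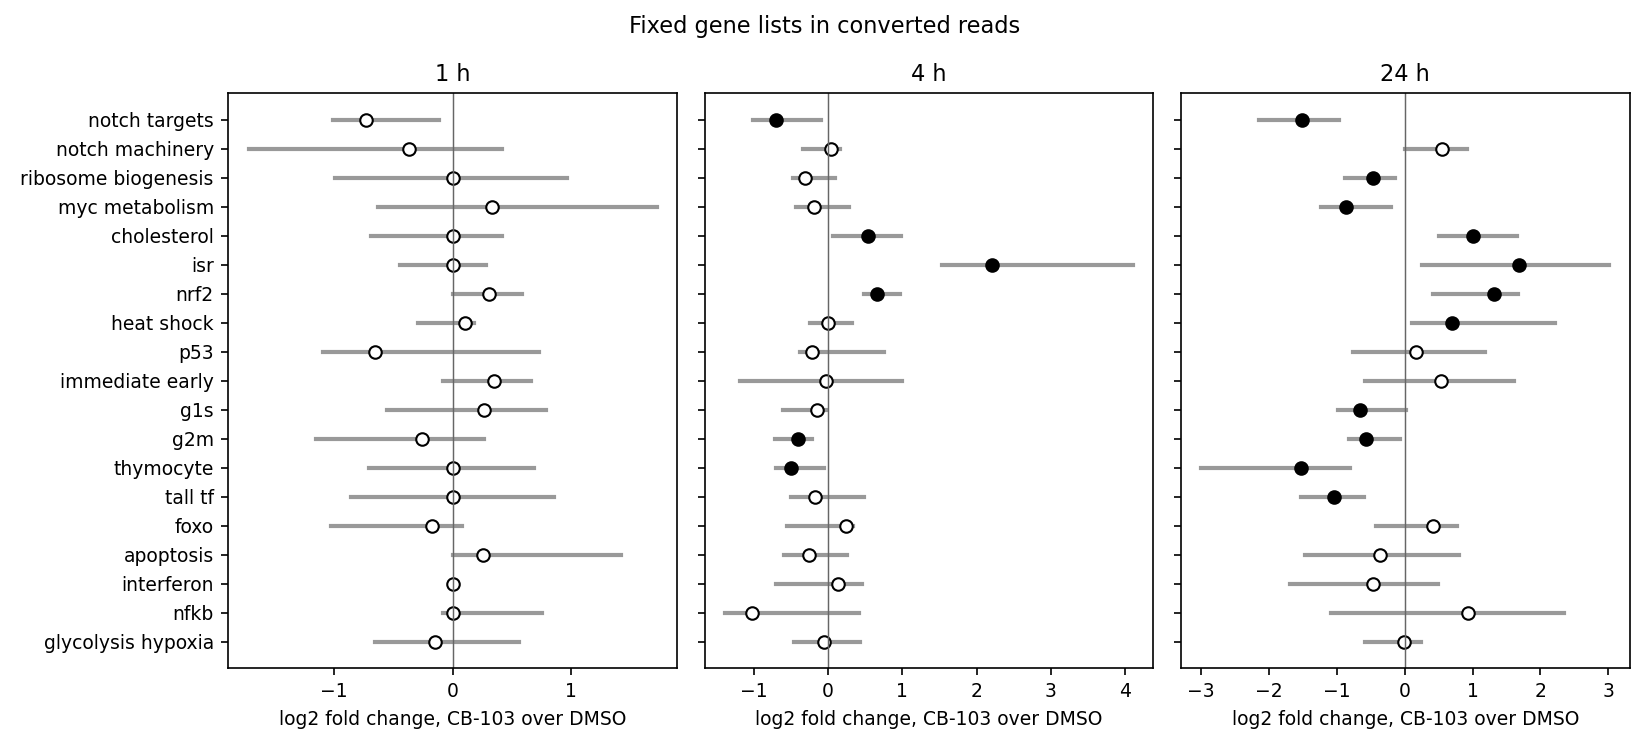
Log2 change of converted reads, CB-103 against DMSO, for the tested genes of each list at 1, 4 and 24 h. Dots are medians over genes, bars run between the quartiles, and filled dots have an adjusted p below 0.05 by camera. The stress list has medians of 2.21 at 4 h and 1.68 at 24 h, and the Notch target list of -0.70 and -1.51.

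In total RNA at 24 h, the Notch target list was lower. HES1 fell by 2.34 ± 0.23 on the log2 scale, from 46.5 ± 17.5 to 9.19 ± 0.950 CPM (SD, n = 3; adjusted p = 3.87e-07), DTX1 by 2.45 ± 0.24 (adjusted p = 2.68e-07) and MYC by 2.02 ± 0.31 (adjusted p = 4.79e-05). HES4 fell by 1.46 ± 0.31, NOTCH1 fell by 1.4997 ± 0.24 and NOTCH3, another Notch receptor, fell by 4.62 ± 1.06, and all 6 calls were kept without any 1 library. IGF1R, a growth factor receptor, had a log2 change of -0.27 ± 0.17 (adjusted p = 0.208), and IL7R, with 21 reads in DMSO and 12 with CB-103, of -0.04 ± 1.21 (adjusted p = 0.985). Notch targets fell in 12 of 16 (13 adjusted over the list alone, median -1.43, adjusted p = 6.57e-08). Other Notch pathway genes rose in 5 of 17 and fell in 0 (5 adjusted over the list alone, median 0.28), not called by camera (adjusted p = 0.0891) but higher by fry (6.3e-07). T-cell identity genes fell in 11 of 16 (11 adjusted over the list alone, adjusted p = 2.3e-06), T-ALL transcription factors in 13 of 19 (13 adjusted over the list alone, 0.000441), G1/S genes in 14 of 24 with 1 rising (16 and 1 adjusted over the list alone, 0.000798), and ribosome biogenesis genes in 15 of 30 with 1 rising (17 and 2 adjusted over the list alone, 0.00179). Metabolic MYC targets fell in 13 of 24 with 1 rising (13 and 1 adjusted over the list alone, adjusted p = 0.00211), but not with an estimated correlation (adjusted p = 0.0669). G2/M genes fell in 12 of 20 with 1 rising (14 and 1 adjusted over the list alone, adjusted p = 0.00288), but not with an estimated correlation (adjusted p = 0.144).

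The lists that camera called higher in total RNA at 24 h were the stress list (14 of 22 rose, 14 adjusted over the list alone, median 1.41, adjusted p = 1.24e-09), NRF2 (9 of 12, 9 adjusted over the list alone, 8.89e-05), cholesterol (13 of 20, 14 adjusted over the list alone, 1.3e-05) and heat shock (7 of 13 with 1 falling, 9 and 1 adjusted over the list alone, 0.000149). By fry immediate early, NF-kappaB and FOXO genes were also higher (adjusted p = 1.92e-06, 1.14e-06 and 0.00211), and apoptosis genes lower (0.0215). Camera within the 6 libraries of 24 h called NF-kappaB too (0.0244). OSGIN1, an NRF2-regulated growth inhibitor, had 0 total reads in DMSO and 114 with CB-103, and FBLN5, a matrix protein, had 41 and 0, again in counts that can hold a read more than once. Of 12272 genes 4692 were called, 2169 higher and 2523 lower. A 2-fold threshold left 2451, and leaving out a library gave 3882 to 4851. Simulated 2-fold changes were recovered in 52% of genes and 4-fold changes in 76.8%. Aryl hydrocarbon receptor genes were not called (5 tested, 2 rising, 2 adjusted over the list alone, adjusted p = 0.464).

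Whether the effect changed with time was tested in converted reads as a difference of log2 changes. From 4 to 24 h the effect on RHOU moved by -3.13 ± 0.42 (SE, n = 3 per group; adjusted p = 0.000700) and on CHAC1 by -6.17 ± 0.86 (adjusted p = 0.00106), CHAC1 having been higher at 4 h, and on HSPA1B by 4.86 ± 0.52. ID3, an inhibitor of helix-loop-helix factors, moved by -2.55 ± 0.45. From 1 to 24 h the effect on HES1 moved by -2.55 ± 0.47 (adjusted p = 0.00675), on HSPA5 by 4.03 ± 0.52 and on HMGCS1 by 3.31 ± 0.59, and from 1 to 4 h that on DDIT3 by 5.47 ± 0.65 (adjusted p = 0.000308) and on JUN by 6.02 ± 0.86. The changes from 1 to 4 h passed in 49 genes (33 higher, 16 lower), from 1 to 24 h in 268 (141 and 127), and from 4 to 24 h in 8 (3 and 5). The balance from 1 to 24 h turned with RLE (145 higher, 179 lower) and with scaling from total reads (113 and 202), and from 1 to 4 h these gave 35 and 29, and 65 and 17. With the replicate as a block these were 1, 127 and 4, and with DESeq2 1024, 1389 and 408. Without 1 library they ranged from 12 (without CB-103 replicate 3 of 4 h) to 214 (without DMSO replicate 2 of 1 h), from 117 (without CB-103 replicate 2 of 24 h) to 488 (without DMSO replicate 2 of 1 h), and from 4 (without CB-103 replicate 2 of 4 h, among others) to 6. Simulated 4-fold changes of the effect were recovered in 0%, 2.15% and 6.45% of genes and 2-fold changes in 0%, so a gene that did not pass is not shown to keep its effect.

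The test of the labelled share asked whether a gene's converted reads changed more than its unconverted reads. Unconverted reads are not only old RNA, because 92.9% of single converted reads carried 2 or more conversions. New RNA with fewer conversions can therefore go uncounted. Conversions per converted read also differed at 24 h, at 2.61 in DMSO and 2.51 with CB-103. At 4 h the share of PSAT1, an enzyme of serine synthesis, was 18.6% ± 4.24 in DMSO and 44.1% ± 0.948 with CB-103 (SD, n = 3; log2 change 2.03 ± 0.23, SE, adjusted p = 0.00576), a call lost in 2 of 6 fits without a library. That of CD63, a tetraspanin, was 5.09% ± 0.582 and 1.84% ± 0.199 (-1.29 ± 0.17, adjusted p = 0.0118), lost in 4 of 6. At 24 h the shares of the metallothioneins MT1X and MT2A, which bind metal ions and share reads with paralogs, were 38.8% ± 6.80 and 38.4% ± 0.403 in DMSO, and 50.6% ± 1.65 and 42.3% ± 2.07 with CB-103 (log2 changes 1.63 ± 0.26 and 1.19 ± 0.10). MT2A was not called without a TMM factor (adjusted p = 0.117). PRSS57, a serine protease, had a share of 7.10% ± 0.216 in DMSO and 0% with CB-103 (adjusted p = 0.00624). At 1 h edgeR called 0 of 1426 genes (37 at an unadjusted p below 0.05), with 0% of simulated 4-fold changes recovered. At 4 h it called 46 of 9439 (38 higher, 8 lower; 74.5% of 4-fold and 14.3% of 2-fold changes recovered), and at 24 h 213 of 9640 (27 and 186; 58.1% and 4.12%). At 4 h the count was 9, 0 and 109 without DMSO replicates 1, 2 and 3 and 16, 1 and 10 without CB-103 replicates 1, 2 and 3. A TMM factor per read type sets the general fall of the labelled share aside: without it 6803 genes were called at 24 h, 6798 of them lower, and 152 at 4 h, 107 of them lower.

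Markers of other cell types were tested only where they passed the read filter, in lists of 12 B-cell, 13 myeloid and 12 stroma genes. Their read levels were not compared, so the numbers tested are no measure of other cells. Of the B-cell list 1 gene was tested in converted and 7 in total reads (adjusted p = 0.174 by camera and 0.000194, lower, by fry at 24 h in total reads, median -0.89, 2 lower, 1 adjusted over the list alone), of the myeloid list 0 and 3, and of the stroma list 1 and 2. The gene of the stroma list tested in converted reads was PECAM1, which leukocytes express as well.

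Positions are given on GRCh38 as the UTR entry with most reads of each gene. HES1 (ENSG00000114315.3) lies on chromosome 3 from 194138234 to 194138732, DTX1 (ENSG00000135144.7) on chromosome 12 from 113096940 to 113098028, and MYC (ENSG00000136997.17) on chromosome 8 from 127740959 to 127742950. RHOU (ENSG00000116574.5) lies on chromosome 1 from 228743741 to 228746664, CHAC1 (ENSG00000128965.12) on chromosome 15 from 40955775 to 40956512, DDIT3 (ENSG00000175197.12) on chromosome 12 from 57516588 to 57516808, and HSPA5 (ENSG00000044574.7) on chromosome 9 from 125234853 to 125236591. In the annotation each of these lies within an annotated UTR, except that the entry of MYC overlaps one.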

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

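The differences between times were tests set before the data were examined. The counts over other splits, the count with a single UTR entry per gene and the comparison of signs with other splits were chosen after the results were seen.

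Each value here is the difference between 2 times of the log2 effect of CB-103 in converted reads, of a named gene whose test of that difference passed. From 1 to 4 h the effect moved up in SESN2 (7.03), JUN (6.02), DDIT3 (5.47), HERPUD1 (5.27), HSPA5 (2.38) and NFKBIA (2.24). From 1 to 24 h it moved up in CXCL8 (9.53), HSPA1B (5.30), HSPA1A (4.47), JUN (4.44), HSPA5 (4.03), DDIT3 (3.94), PPP1R15A (3.72), HERPUD1 (3.38), HMGCS1 (3.31), VEGFA (3.06), MSMO1 (2.75), NFKBIA (2.27), DNAJA1 (2.18), INSIG1 (1.47) and FTH1 (1.27). Over the same span it moved down in AEN (-6.04), RHOU (-3.75), HES1 (-2.55), UNG (-2.33) and BCL11B (-1.88). From 4 to 24 h it moved up in HSPA1B (4.86) and HSPA1A (4.38) and down in CHAC1 (-6.17), RHOU (-3.13) and ID3 (-2.55). HSPA1A and HSPA1B can share reads. SESN2, CXCL8 and AEN had few converted reads at 1 h, so the sizes of their differences from 1 h are uncertain. SESN2 had 3, 1 and 1 reads in the DMSO libraries of 1 h and 1, 0 and 0 with CB-103. AEN had 1, 0 and 0 against 20, 2 and 2, and CXCL8 had 1, 0 and 3 against 6, 1 and 0.

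In the other genes a group at 1 h held 0 converted reads, so the fitted differences depend on the prior count and are no bounds. From 1 to 4 h these were ZNF266 (11.92), ATP6AP2 (11.78), ARMC8 (11.64), TSFM (11.37) and PDLIM2 (11.003), and TPI1 (-12.13), GUSB (-11.90), FCHO1 (-11.58), SLC17A9 (-11.46), CNOT10 (-10.98), AQR (-10.74), PSMF1 (-10.49) and DDOST (-10.32). From 1 to 24 h they were ARMC8 (12.01), ZNF266 (11.48), TSFM (11.44), CDC40 (11.32), UBE2W (11.28), ATP6AP2 (11.24), FURIN (11.20) and PDLIM2 (9.89), and SLC17A9 (-13.42), BCL11A (-12.94), TPI1 (-12.68), FCHO1 (-11.87), COQ8A (-11.29), ZC3HC1 (-11.26), GUSB (-11.21), CNOT10 (-11.02), PSMF1 (-10.51), TMEM161B (-10.39), AQR (-10.35) and DDOST (-10.16).

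Other splits of the libraries were drawn 100 times for each change between times, the real one included. From 1 to 4 h 11 of the 100 gave at least the real 49 genes (highest other 129), and from 4 to 24 h 5 gave at least the real 8 (highest other 49), so chance was not excluded for either count. From 1 to 24 h 4 gave at least the real 268 (highest other 322), a share under 0.05 that was not adjusted for the number of tests. The libraries of both times were regrouped, so the effect at 24 h alone can bring this about. The share therefore does not show that the effect changed from 1 h. The 10 splits at each time are too few for a share under 0.05. For converted reads at 1 h 4 of the 10 gave at least the real 177 genes (highest other 250). At 4 h the real 70 stood against a highest other of 1, and at 24 h the real 636 against 0, each reached by 1 of 10 splits. For total reads the real 0, 945 and 4692 stood against 779, 0 and 290, reached by 10, 1 and 1 splits. The split at 1 h that called 779 genes set DMSO replicates 1 and 3 with CB-103 replicate 1 against DMSO replicate 2 with CB-103 replicates 2 and 3, which points to a structure of those samples that the labels do not name. At 24 h the split with 290 calls set DMSO replicate 1 with CB-103 replicates 1 and 3 against the others. Residuals of total reads at 24 h correlated between DMSO replicate 1 and CB-103 replicate 3 (0.28). Those of DMSO replicate 3 and CB-103 replicate 2 did too (0.26). An unnamed structure at 24 h is therefore not excluded either. For labelled shares the real 0, 46 and 213 stood against 0, 0 and 0, reached by 10, 1 and 1. For lists in converted reads the real 0, 6 and 11 stood against 0, 3 and 8, and in total reads the real 0, 5 and 11 against 1, 4 and 9, each reached by 10, 1 and 1. The other splits called 1 to 3 lists at 4 h and 3 to 8 at 24 h in converted reads. In total reads they called 1 to 4 and 0 to 9. A list call by camera at 4 or 24 h therefore does not by itself mark the real grouping.

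Genes were called in converted reads at 1 h although none was called in total reads. Counting a read once per overlapping UTR entry is a candidate explanation, since 3 of the 177 genes were called with a single UTR entry per gene, but that setting also leaves fewer reads, with a median of 15 instead of 36 converted reads over the 6 libraries for a called gene. An early response to CB-103 stays open: 68.4% of the called genes (95% Clopper-Pearson interval 61.0 to 75.1) had the same sign in total reads, above the 60% set beforehand, but the 9 other splits gave 51.8% to 66%. That comparison was added after the result was seen, and with it the reading changed from met to open. Converted reads are part of total reads, so some sharing of sign is built in. At 4 h 55.4% had the same sign in converted reads.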

How the results depend on the processing

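The single UTR entry, the authors' size factors and the fits without the 1 h libraries were alternatives chosen after the data were seen. The cause of the changes below was not tested, except that leaving out libraries or UTR entries leaves fewer reads and that the 2-fold threshold can only lower a count. RLE scaling and both other filters kept each count within 1.5 times, and counts from the summed UTR entries equalled those of the gene tables. Values are for converted reads at 1, 4 and 24 h unless named.

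DESeq2 gave 1191, 516 and 1970 genes, 1024, 1389 and 408 for the changes from 1 to 4, 1 to 24 and 4 to 24 h, and 1481 for total reads at 4 h. Only the 6 libraries of a time gave 0 (of 1426 tested, 34 of the 177 among them), 615 and 2849, and 1725 in total reads at 4 h. The replicate block gave 59, 30 and 405, changes of 1, 127 and 4, and 502 in total reads at 4 h. Scaling from total reads gave 352 at 1 h, 1778 at 24 h and a change from 1 to 4 h of 82, and the authors' size factors gave 351, 1683 and 83. A single UTR entry gave 3, 308 and 1784, changes of 104 (1 to 4 h) and 88 (4 to 24 h), and labelled shares of 218 at 4 h and 399 at 24 h. Without the 1 h libraries there were 637 at 4 h and 2766 at 24 h. The 2-fold threshold left 374 and 2451 in total reads at 4 and 24 h. Without a TMM factor the labelled shares gave 152 at 4 h and 6803 at 24 h. Of the lists in total reads fry called 29 against 16 by camera, and an estimated correlation kept 12, while in converted reads the counts were 17, 17 and 13.

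Leaving out each library in turn gave 208 to 351 genes at 1 h, 29 to 47 at 4 h and 208 to 377 at 24 h, changes of 12 to 214, 117 to 488 and 4 to 6, 517 to 625 in total reads at 4 h, and 0 to 109 labelled shares at 4 h. Total reads at 1 h stayed at 0 genes by edgeR (349 to 1528 at an unadjusted p below 0.05). The log2 changes that turned were all of genes not called. In converted reads at 1 h these were DTX1 (-7.04 to 6.29), IGF1R (-3.14 to 0.38, and 0.17 without DMSO replicate 3, 0.23 without CB-103 replicate 3) and HES1 (-0.17 with scaling from total reads, -0.16 with the authors' size factors). In converted reads at 4 h they were HES4 (-0.20 to 0.0082) and MYC (-0.39 to 0.047, and 0.018 without DMSO replicate 2). In total reads at 1 h they were HES1 (-0.093 to 0.033, and 0.024 without DMSO replicate 3), NOTCH1 (-0.051 to 0.33), NOTCH3 (-0.35 to 0.0089), IL7R (-1.15 to 2.23) and MYC (-0.17 to 0.10, -0.091 without DMSO replicate 2, and -0.00025 with a single UTR entry). In total reads at 24 h IL7R ranged from -2.93 to 0.57, with 0.11 and 0.43 without DMSO replicate 1 and CB-103 replicate 2, 0.0012 with RLE, 0.0041 with DESeq2 and 0.085 with a single UTR entry.

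Depth limits converted reads most at 1 h, where 2124 of the 9875 tested genes had no converted read and the median per gene and library was 0.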

Other observations

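The gene families and genes in the first paragraphs, and the tests of the lower labelled share, were chosen after the data were seen. The test of matched lists was set before its result was seen.

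Both metallothioneins tested in converted reads, which bind zinc and copper, rose at 4 and 24 h, and 2 of the 3 tested in total reads did. In converted reads MT2A rose by 3.40 ± 0.40 on the log2 scale at 4 h and by 3.46 ± 0.40 at 24 h (SE, n = 3 per group; adjusted p = 2.57e-05 and 1.38e-05), and MT1X by 3.70 ± 0.47 and 4.52 ± 0.50, though these paralogs can share reads. SLC30A1, a zinc exporter, had a log2 change of 1.94 ± 0.39 at 4 h (adjusted p = 0.0149), which was not called with scaling from total reads (0.0592), with the replicate as a block (0.0706) or in 5 of the 6 fits without a library. RASGRP1, an activator of Ras in T cells, rose by 2.78 ± 0.39 at 4 h. In total reads at 24 h 17 of 33 standard proteasome subunits rose and 0 fell (median 0.55), with PSMC4 at 1.23 ± 0.17, while 3 of 3 immunoproteasome subunits fell (median -1.57). Family values in total reads are relative to the other RNA counted, and small rises need not be gains in amount. In converted reads at 24 h PSMB8 fell by 2.00 ± 0.40, a call lost without CB-103 replicate 2 (adjusted p = 0.0521). The median of the standard subunits in converted reads was 0.57 and turned to -0.03 with scaling from total reads, where the median of all genes was -0.64.

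Genes of the lymphocyte GTPase family GIMAP fell in 7 of 7 in total reads at 24 h (median -2.38) and in 5 of 7 in converted reads (median -2.42, and -3.03 with scaling from total reads), with GIMAP6 at -2.93 ± 0.38. The family shares sequence, so the values of single members are uncertain. CCR9, a homing receptor of thymocytes, fell by 4.16 ± 0.65, CD3G, a chain of the T-cell receptor complex, by 2.12 ± 0.37, MFNG, a glycosyltransferase that modifies Notch, fell by 2.90 ± 0.48 and GBP4, an interferon-induced GTPase, by 4.77 ± 0.65, all in converted reads at 24 h (SE, n = 3 per group). In total reads at 24 h 23 of 38 nuclear genes of mitochondrial complex I fell and 1 rose (median -0.75), while in converted reads 1 fell and 0 rose, or 22 fell with scaling from total reads. Of 18 aminoacyl-tRNA synthetases 11 rose and 1 fell in total reads (median 0.66), while in converted reads 2 rose and 0 fell, or 1 rose and 2 fell with that scaling. Of 28 histone genes 10 rose and 1 fell in total reads (median 1.503), with HIST1H2BG at 3.02 ± 0.31, though these genes share sequence. In converted reads 0 of 11 were called, and their median of 0.31 turned to -0.28 with scaling from total reads. Of 73 cytosolic ribosomal protein genes 14 fell in converted reads at 24 h and 0 rose (median -0.82), or 53 with scaling from total reads (median -1.43), while in total reads 5 fell (median -0.12), or 3 fell and 1 rose with RLE.

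Notch target genes were lower as a list after CB-103 at 4 and 24 h, though the call in converted reads at 4 h, with 1 of 13 genes called, was lost with an estimated correlation (adjusted p = 0.140) and by fry (0.0860). A general fall of transcripts of like turnover and level was argued against: of 10000 random lists matched on the labelled share and level in DMSO, 0% had a median as low in converted reads at 4 h (-0.70, against a lowest 2.5th percentile of -0.37), 0% at 24 h (-1.51 against -0.60) and 0% in total reads at 24 h (-1.43 against -0.55). The random lists drew genes independently, so these percentages leave out how list members vary together across libraries. They show only that the list lay lower than matched genes in these libraries. A response to the compound, which the design names, stays open as a hypothesis, as do effects of the stress responses that rose in the same libraries, which were not tested.

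The labelled share was lower in CB-103 libraries at 24 h. A few genes taking most of the labelled reads was argued against, because 97.2% of the 9640 tested genes had a lower share. Fewer conversions per labelled transcript may account for part: conversions per converted read went from 2.61 to 2.51, which predicted, under an assumed Poisson distribution with at least 2 conversions, a share of 29.2% against 21.5% seen and 34.9% in DMSO, all with a single UTR entry per gene (19.9% and 33.2% in the deposited gene tables). Because that distribution was assumed, the prediction excludes nothing, and less RNA synthesis and less uptake of 4sU cannot be told apart in these data.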
